A study of Mus musculus with 8 samples.

How the data were processed

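The series holds 8 droplet single-cell RNA libraries of mouse spleen germinal centre (GC) B cells, 4 from Dtx1+/+ animals (WT) and 4 from Dtx1-/- animals (KO). Per the labels' protocols, cells were enriched with a bead kit based on peanut agglutinin (PNA), a lectin that binds GC B cells, at day 10 after immunization. They were then sorted by flow cytometry, per the series' design text, and 10000 cells were loaded for each library, per the labels' protocols. How many mice a library holds, their sex and the immunogen are not stated in the labels.

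The deposited values are unnormalized UMI counts (counts of distinct transcript molecules) per gene and cell barcode, written by Cell Ranger 6.0.0 per the file headers and aligned to mm10 per the submitters' processing notes. Those notes also name R 4.3.1 and Seurat 4.3.0, but the count files carry no step made with them. The 8 files list the same 32285 genes and hold 62029 barcodes that had already been called as cells. Total counts ran from 51994877 to 72695385 UMIs per library. For GC B-like sums edgeR estimated a common coefficient of variation between libraries, beyond counting error, of 0.0415. Counting error adds to it, most for genes with few counts.

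Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which removed 3079 and 1872 barcodes by the respective rule and left 57775 cells. Scrublet doublet scores (scanpy) were computed per library with an expected rate of 6%. The automatic threshold marked only 9 barcodes (0.0145%), so the doublet caller did not work here. Doublets therefore remained in the data, and an alternative removed the 6% of cells with the highest scores (3265 cells). In cells that carry Xist and Y-linked UMIs together, the implied doublet rate was 4.88% ± 0.900 in WT and 6.59% ± 0.681 in KO (SD, n = 4 libraries each).

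Clusters were made with scanpy 1.11.5 from 2000 variable genes ranked within library, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no integration across libraries. Immunoglobulin, T cell receptor, mitochondrial, ribosomal protein and sex-linked genes and Dtx1 were left out of the variable genes. The 20 clusters were named only from marker genes that had been fixed beforehand, and the suffix "-like" marks such names. Of the kept cells, 48738 fell in GC B-like clusters. Free RNA in the droplets was not removed, since the files hold no empty barcodes.

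The library was the replicate in each test. Counts were summed per library over the GC B-like cells, over all kept cells, and over each GC state with at least 20 cells per library, and tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test with robust dispersion, Benjamini-Hochberg adjusted p below 0.05, genotype as the only term). The difference of the change between light zone-like and dark zone-like cells was tested as an interaction in 1 edgeR model with the library as block. The same kind of model tested the difference between male and female cells. Shares of cells were compared by two-sided exact permutation tests over the 70 assignments of the libraries (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). The smallest p this design allows is 0.0286. Adjustment covered all classes, all isotypes or both usage measures as 1 family.

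The isotype of a cell was the heavy chain constant gene with most UMIs, given at least 2 UMIs and over 50% of the cell's heavy chain constant UMIs, and the variable genes were called by the same rule. Ighm and Ighd were counted together as unswitched. Cells with at least 2000 UMIs were called female with 2 or more Xist UMIs and no UMI of 4 Y-linked genes, and male with no Xist UMI.

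Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation, with fry beside them. Of 39 lists, 37 had at least 3 tested members. The markers of NK cells and of platelets did not. The genes named in the text follow a rule. They are Dtx1, then the 12 genes with the largest change in each direction among genes past the edgeR test, with non-overlapping libraries and a mean of at least 10 CPM (UMIs of a gene scaled to a common library total). Variable region, T cell receptor, Xist, Tsix, Y-linked and unnamed genes are left out of these. Up to 4 members follow from each list called by camera, in its direction, and up to 2 called members from each other list. Named genes that fall outside this rule are said to be so, and 1 gene that the rule names is not reported here.

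The groups, tests, lists, markers, naming rule and most alternatives were chosen before the data were examined. The alternatives were other scalings, tests (DESeq2 1.42.0, limma voom), filters, doublet handling, cluster resolutions, cells thinned to 2000 UMIs before clustering, cell numbers, equal weights of GC states, a replicate block, and leaving out each library in turn. Fits on male or female cells alone, and clusters made without 6045 genes that had changed in GC B-like, light zone-like or dark zone-like cells, were added afterwards. Gene positions are from GENCODE vM21 on mm10, which gave coordinates for 13086 of 13105 tested genes.

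The procedure was tested on simulated counts for the 13105 genes of the GC B-like comparison, with 50 genes changed at each size. It recovered 35 at 1.2-fold, 39 at 1.5-fold, 47 at 2-fold and 47 at 4-fold, and 13 of 181 calls (7.18%) were false. For the state interaction, simulated over 6926 genes, it recovered 170 of 200 changed genes among 176 calls. A simulated shift of the cholesterol synthesis list was found by camera, with 0 of 38 other lists called. Simulated genes were drawn independently of each other, so this does not test false calls for lists whose members move together. Simulated shares without a difference gave an exact permutation p under 0.05 in 2.65% of 2000 sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

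Camera p-values weigh the members of a list against other genes, and chi-square p-values count single cells. All other p-values measure only the spread between libraries. That spread may be technical, because the labels do not say whether the libraries of a genotype come from separate animals. Ighv usage was alike among the libraries of a genotype (chi-square over degrees of freedom 1.02 in WT and 0.941 in KO). Between male and female cells of a genotype it differed (13.5 in WT and 4.40 in KO). This argues for libraries drawn from 1 pool of cells per genotype. The p-values may then not cover differences between mice. Clones could not be told apart, because the libraries hold gene expression without assembled receptors.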

Results

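Single-cell RNA was measured in GC B cells enriched from mouse spleen at day 10 after immunization, from 4 WT libraries (Dtx1+/+) and 4 KO libraries (Dtx1-/-). The series compares the genotypes to ask what Dtx1 does in GC B cells. The WT libraries held 8000, 7600, 7363 and 7647 barcodes with 56363026, 55500158, 52363089 and 64623502 UMIs, in the order of their numbers. The KO libraries held 7872, 8314, 7957 and 7276 barcodes with 64293434, 72695385, 71983430 and 51994877 UMIs. Kept cells had a median of 6238 UMIs in WT and 7003.5 in KO. GC B-like clusters held 21790 cells of WT and 26948 of KO, 84.4% of all kept cells. Within a genotype the libraries did not differ in Ighv gene usage beyond sampling of cells, with a chi-square over degrees of freedom of 1.02 among the 4 WT (p = 0.409) and 0.941 among the 4 KO libraries (p = 0.727). Parts of 1 pool per genotype would be alike in this way, so the p-values between libraries given below may not cover differences between mice. Expression profiles of library pairs differed beyond sampling within a genotype (5.86 to 18.3 on the same scale) and more between genotypes (28.2 to 63.8).

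Dtx1, a ubiquitin ligase of the Deltex family that is linked to Notch signalling, was lower in the GC B-like cells of all 4 KO libraries but was still detected there. The gene (ENSMUSG00000029603, chromosome 5, 120680202 to 120711927, minus strand, mm10) measured 78.5 ± 1.56 CPM in WT and 40.4 ± 1.27 CPM in KO (SD, n = 4 libraries each). The change was -0.96 on the log2 scale (SE 0.03, edgeR adjusted p = 1.7e-16). All 4 KO libraries also lay below WT in memory-like B cells, at 49.7 ± 8.25 against 88.0 ± 6.77 CPM, and in neutrophil-like cells, at 25.9 ± 9.27 against 78.2 ± 16 CPM (exact p = 0.0286 for each, 0.0571 adjusted over 6 classes). Naive-like B cells measured 69.0 ± 13.6 CPM in WT and 76.8 ± 11.6 in KO (exact p = 0.429), T cell-like cells 144 ± 16.9 and 121 ± 45.8 (exact p = 0.371), and macrophage-like cells 13.3 ± 8.12 and 8.88 ± 7.34 (exact p = 0.514). Relative to GC B-like cells of the same library, the naive-like level was 1.12 higher in KO than in WT on the log2 scale (exact p = 0.0286, 0.0429 adjusted over 3 classes). Over all UMIs of a library, the WT libraries held 75.1, 76.1, 76.5 and 73 CPM and the KO libraries 39.99, 37.9, 41.0 and 38.7 CPM, a mean of 52.4% of WT (exact p = 0.0286). Where the counted part of the transcript lies relative to the deleted part is not stated, so the remaining UMIs say nothing about the protein.

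**Figure D1:**
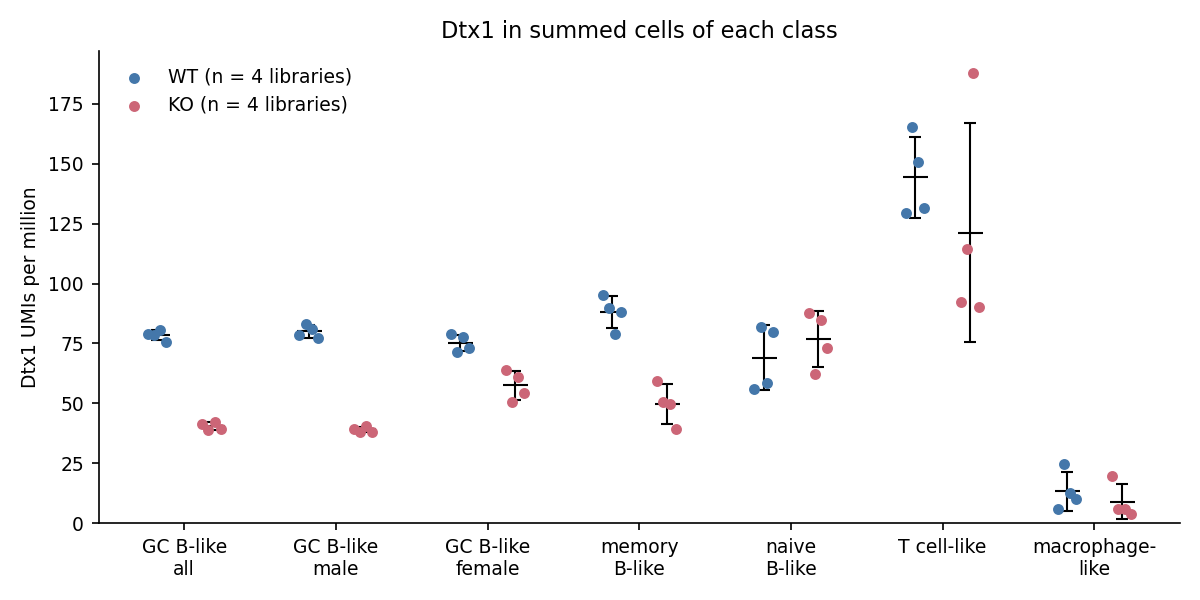
Dtx1 in CPM (linear axis) in the summed cells of each class, with points for libraries, horizontal lines for the mean and error bars for the SD of 4 WT and 4 KO libraries. GC B-like cells averaged 78.4 CPM in WT and 40.5 in KO by class sums, while naive-like cells averaged 69.0 and 76.8.

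The comparison of KO with WT GC B-like cells asked which genes depend on the Dtx1 genotype during the GC reaction. The transcription factor genes Fos, Egr1, Jun and Myc and the genes Ier2 and Ppp1r15a, which can answer quickly to receptor signals or stress, were among the genes with the largest rises in KO. The antibody constant region genes Ighg2b and Ighg3 were lower. Cxcr4, the receptor that holds cells in the dark zone, was lower as well. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) rose from 5.49 to 15.5 CPM, a log2 change of 1.5 (SE 0.05, edgeR adjusted p = 1.5e-15). Egr1 rose by 0.94 from 39.6 to 76.0 CPM (adjusted p = 1.5e-15) and Myc by 0.69 from 30.3 to 48.9 CPM (adjusted p = 3.1e-10). Ighg2b changed by -2.08 (43.0 to 10.1 CPM, adjusted p = 3.2e-07), Ighg3 by -1.35 (69.6 to 27.2 CPM, adjusted p = 2.7e-17) and Cxcr4 by -0.65 (61.3 to 39.1 CPM). The Ighg genes share near-identical sequence, so the split of UMIs among them is uncertain.

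The other genes with the largest rises were Sh2d2a (0.96), an adaptor of lymphocyte signalling, Parm1 (0.92), Rilpl2 (0.76), the kinase gene Matk (0.76), Chtf8 (0.74) and Il4i1 (0.71), an amino acid oxidase of activated B cells. Other large falls were in Sap25 (-1.11), the mitochondrial leucyl-tRNA synthetase gene Lars2 (-1.03), the phosphodiesterase gene Pde2a (-0.99), the DNA repair helicase gene Brip1 (-0.95), Grm6 (-0.73), Cacna1i (-0.69), Itgb3 (-0.68) and Mllt6 (-0.67). Of 13105 tested genes, 5593 passed edgeR, 2808 higher and 2785 lower in KO, and most changes were small, with a median absolute log2 change of 0.20 over the called genes. At least 1.5-fold changes were reached by 270 called genes upward and 411 downward, and 2-fold changes by 86 and 79. All 4 KO libraries lay apart from all 4 WT libraries for 38.8% of tested genes, where chance gives 2.86%. Immunoglobulin variable genes, 229 of them tested, were called in 98 cases upward and 29 downward. They account for 67 of the called genes with 2-fold changes. Xist, the RNA of the inactive X of female cells, fell from 448 to 61.7 CPM, and 4 of 8 tested Y-linked genes rose while 1 fell, so the genotypes also differed in the sex of their cells.

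**Figure D2:**
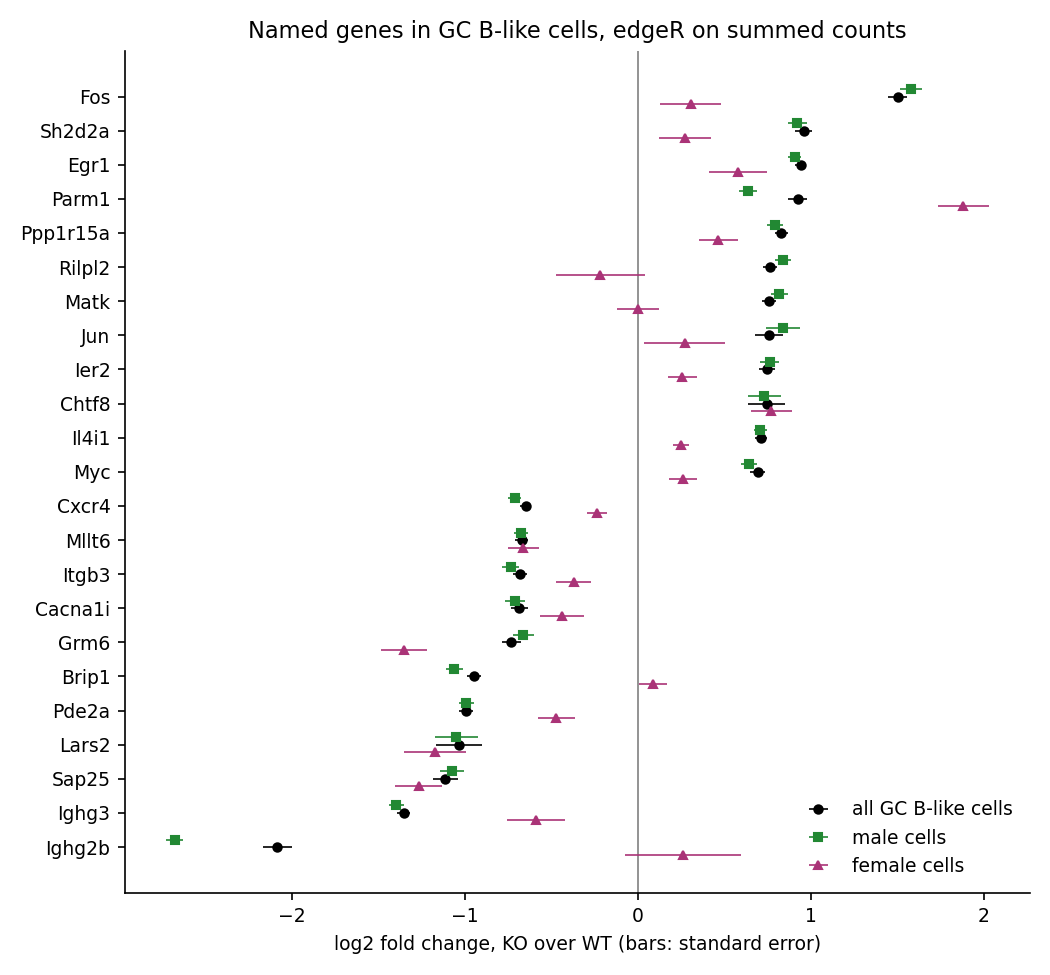
Log2 fold changes, KO over WT, with standard errors for the named genes with the largest rises and falls, in all (circles), male (squares) and female (triangles) GC B-like cells of 4 libraries per genotype. Fos lies at 1.5 in all GC B-like cells and Ighg2b at -2.08, while Brip1 lies at -1.06 in male and 0.09 in female cells.

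Several gene groups rose or fell together in KO GC B-like cells. The clearest was cholesterol synthesis, with 19 of 20 tested members higher (20 adjusted over the list alone), among them Hmgcs1, an early enzyme of the pathway, from 78.9 to 115 CPM (log2 change 0.55), Insig1 (0.68), Cyp51 (0.52) and Msmo1 (0.51). The camera test gave the list an adjusted p of 5.6e-35, and 0.00725 with an estimated correlation. Light zone markers rose in 17 and fell in 1 of 19 (the same numbers adjusted over the list alone, adjusted p = 1.2e-28, and p = 0.00725 with an estimated correlation), with Cd83, a surface protein of light zone cells, going from 265 to 413 CPM (log2 change 0.64). CD40 and NF-kB genes rose in 20 and fell in 3 of 27 (the same over the list alone, adjusted p = 1.0e-13, and p = 0.0236 with an estimated correlation), with Relb (0.49), Bcl3 (0.46) and Nfkbia (0.44). These lists share 10 tested genes with each other. In female cells light zone markers had a median of 0.02. CD40 and NF-kB genes went down there (median -0.19, camera adjusted p = 0.0018, but p = 0.318 with an estimated correlation). Bcl3 (-0.60) and Nfkbia (-0.24) were called lower there by edgeR, and Relb (-0.047) was not called. Glycolysis genes rose in 14 and fell in 2 of 21 (the same over the list alone, adjusted p = 7.2e-11, and p = 0.00725 with an estimated correlation), with the lactate transporter Slc16a3 (1.39), Ldha (0.43), Tpi1 (0.41) and Pkm (0.39). Dark zone markers fell in 6 and rose in 0 of 12 (the same over the list alone, adjusted p = 1.9e-07, and p = 0.0103 with an estimated correlation), with Ccdc88b (-0.54) and Nuggc (-0.17) beside Cxcr4 (-0.65). Dark zone markers did not fall in female cells, with a median of 0.08 against -0.09 in male cells (female camera direction up, adjusted p = 0.132; difference between the sexes 5.4e-11, and p = 0.0475 with an estimated correlation).

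A further 7 lists were called by camera but not with an estimated correlation. Immediate early and handling stress genes rose in 13 and fell in 4 of 22 (the same over the list alone, adjusted p = 1.5e-10, and p = 0.0683 with an estimated correlation), with Fosb (1.56) and Junb (0.44) beside Fos and Egr1. MYC targets rose in 22 of 32 and fell in 0 (22 and 1 adjusted over the list alone, adjusted p = 7.3e-07, and p = 0.394 with an estimated correlation), with Ppan (0.42), Eif5a (0.30) and Srm (0.29). Unfolded protein response genes rose in 9 and fell in 3 of 22 (adjusted p = 0.0180, and p = 0.394 with an estimated correlation), with Xbp1 (0.43), Herpud1 (0.35), Dnajb9 (0.32) and Hspa5 (0.24). Of 21 mTORC1 and nutrient genes 12 rose and 4 fell (12 and 5 adjusted over the list alone, adjusted p = 0.0248, and p = 0.144 with an estimated correlation), with Shmt1 (0.39), Slc7a5 (0.31), Phgdh (0.20) and Shmt2 (0.19). Chromatin regulators fell in 18 and rose in 4 of 26 (adjusted p = 3.5e-04, and p = 0.381 with an estimated correlation), with the histone methyltransferase gene Kmt2d (-0.54), Crebbp (-0.32) and Arid1a (-0.29). Kdm6a, an X-linked gene that escapes X inactivation, changed by -0.37 in all GC B-like cells, -0.11 in male and 0.01 in female cells. Mitochondrially encoded genes fell in 11 and rose in 0 of 13 (adjusted p = 0.0051, and p = 0.407 with an estimated correlation), with mt-Co1 (-0.20), mt-Nd5 (-0.17), mt-Cytb (-0.16) and mt-Nd1 (-0.15). Signs of cell quality moved with the genotype as well. The median mitochondrial share of a barcode was 2.57% to 2.72% in the WT and 2.26% to 2.30% in the KO libraries, and barcodes below 500 genes numbered 469 to 533 and 258 to 280. T cell markers rose in 2 of 5 (Trac 0.82 and Lck 0.51, adjusted p = 0.00827, and p = 0.198 with an estimated correlation), while T cell-like cells made up a smaller share of the KO libraries. For the lists given without it, the counts adjusted over the list alone were the same, and 12 of 37 tested lists were called by camera and 5 with an estimated correlation. Among the 35 splits of the libraries, 4 gave as many lists by camera, the real one included, and 1 gave as many with an estimated correlation.

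**Figure D3:**
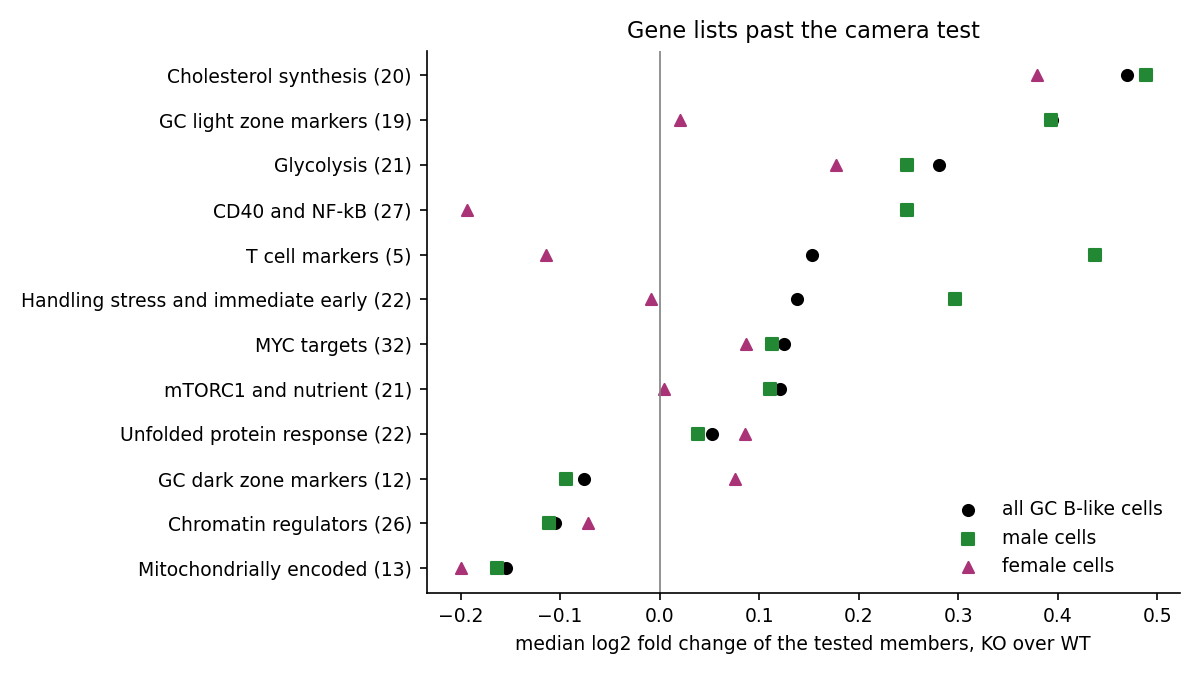
Median log2 fold change, KO over WT, of the tested members (numbers in brackets) of each list called by camera, in all (circles), male (squares) and female (triangles) GC B-like cells. Cholesterol synthesis has medians of 0.47, 0.49 and 0.38 in this order, and light zone markers 0.39, 0.39 and 0.02.

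The KO libraries held a larger share of GC B-like cells and fewer naive-like B and T cell-like cells, and their GC cells were shifted from dark zone-like to light zone-like. These shares come after bead enrichment and sorting, so they describe what passed the sort. GC B-like cells made up 90.1% ± 0.385 of KO and 78.3% ± 0.779 of WT cells (SD, n = 4 libraries each, adjusted exact p = 0.0338, as for the other shares here unless another is given). Naive-like B cells made up 1.11% ± 0.0658 in KO and 8.60% ± 0.328 in WT, T cell-like cells 0.378% ± 0.0200 and 1.76% ± 0.0485, and macrophage-like cells 2.40% ± 0.274 and 5.55% ± 0.985. Neutrophil-like cells made up 0.716% ± 0.0635 in KO and 0.889% ± 0.0878 in WT, and memory-like B cells 2.65% ± 0.0884 and 2.32% ± 0.226 (adjusted exact p = 0.0929). Because zone markers themselves changed, clusters were also made without the changed genes, a choice made after the result was seen. Light zone-like cells were then 9.99% ± 0.483 of KO and 8.65% ± 0.421 of WT GC B-like cells (adjusted exact p = 0.0457), and no cluster was named dark zone-like or memory-like. With all genes, light zone-like cells were 10.8% ± 0.404 in KO and 7.04% ± 0.425 in WT, and dark zone-like cells 9.27% ± 0.365 and 11.8% ± 0.314. The ratio of dark zone-like to light zone-like cells was 0.856 ± 0.0216 in KO and 1.68 ± 0.135 in WT. In female cells alone the direction turned, with a ratio of 2.58 ± 0.450 in KO and 1.64 ± 0.157 in WT (adjusted exact p = 0.0619), dark zone-like cells 3.32 points higher and light zone-like cells at -1.32 points. S phase-like cells were 27.5% ± 1.45 in KO and 24.7% ± 0.596 in WT, a difference of 2.83 points that became -0.119 without the changed genes and -0.392 at a finer cluster resolution. G2/M-like cells were 15.1% ± 1.11 and 15.2% ± 1.11 (adjusted exact p = 0.886), and 1.16 points higher in KO with thinned cells (adjusted exact p = 0.0321). These phase names rest on marker genes alone, free RNA was not removed, and depth was higher in KO, so no cycling is read from them.

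The macrophage-like difference of -3.15 points was -1.07 with the strict cell filter, -1.06 in thinned cells and -1.43 in male cells alone, and the naive-like difference of -7.49 points was -3.67 at a finer cluster resolution, all still called. Some share calls changed when 1 library was left out. The macrophage-like, neutrophil-like and cluster 11 differences were not called without KO 1, KO 2, KO 3 or KO 4 (adjusted exact p between 0.0675 and 0.101), and the S phase-like difference was not called without WT 1, WT 2, WT 3 or WT 4 (adjusted exact p between 0.0619 and 0.0675). The memory-like difference was called without WT 1 (adjusted exact p = 0.0338, at most 0.124 without another). Cluster 11, led by Slpi, Batf and Srm, was not named by the markers and held 2.55% ± 0.173 of KO and 1.94% ± 0.260 of WT cells, with a median of 22005 UMIs, 3.28 times that of its library. Cluster 19, also unnamed and led by genes that include Rag1, Il7r, Sox4 and Myb, held 0.133% ± 0.0850 of KO and 0.681% ± 0.0419 of WT cells.

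**Figure D4:**
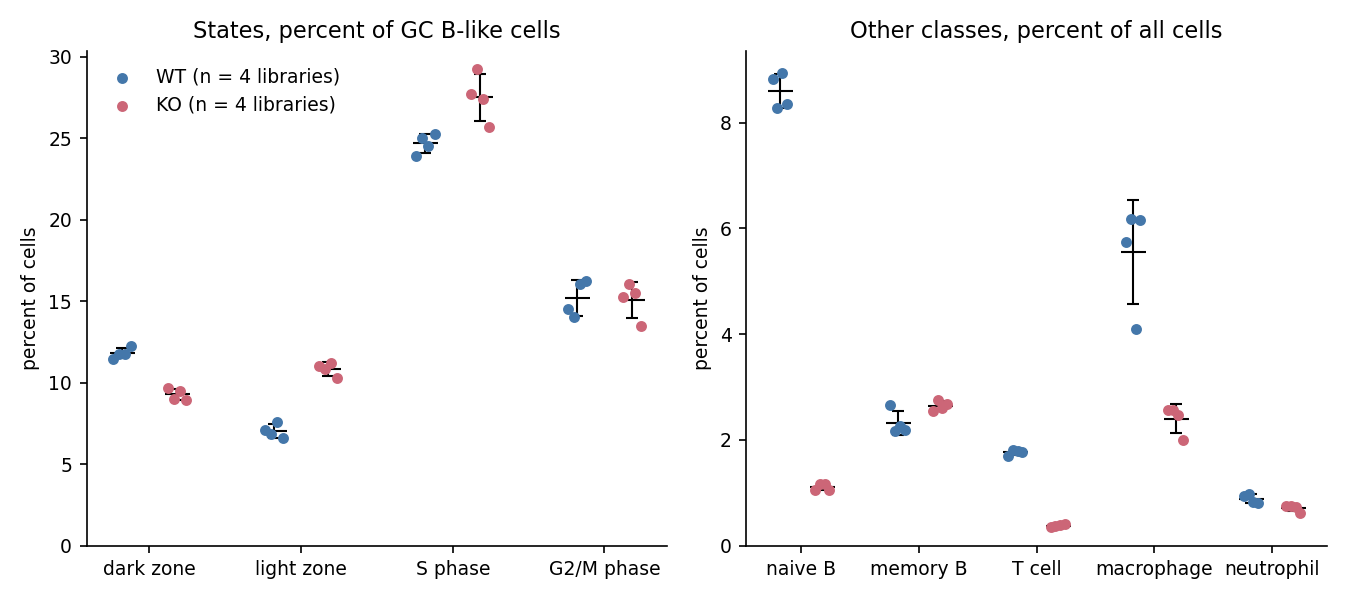
Shares of cell classes in percent, with points for libraries, horizontal lines for the mean and error bars for the SD of 4 WT and 4 KO libraries. Light zone-like cells average 10.8% of GC B-like cells in KO and 7.04% in WT, and naive-like B cells 1.11% and 8.60% of all cells.

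Tests within each GC state asked whether the genes changed inside a state or only with the mix of states. Fos rose in every named state, by 1.5 in dark zone-like, 1.3 in light zone-like, 1.65 in S phase-like and 1.23 in G2/M-like cells on the log2 scale. Hmgcs1 rose by 0.40, 0.31, 0.49 and 0.55 in the same order, and the cholesterol synthesis list had medians of 0.37, 0.29, 0.41 and 0.43. Light zone markers had a median change of 0.19 in dark zone-like, 0.43 in S phase-like and 0.29 in G2/M-like cells (camera with an estimated correlation p = 0.0502, 0.00235 and 0.029). They did not rise within light zone-like cells, whose cluster these same genes name (median 0.05, camera direction down, adjusted p = 0.441). CD40 and NF-kB genes had a median of -0.15 there (camera adjusted p = 0.0038, and p = 0.105 with an estimated correlation). Dtx1 changed by -0.73 in dark zone-like, -1.07 in light zone-like, -1.06 in S phase-like and -1.0 in G2/M-like cells. By edgeR, 1716 genes were called in dark zone-like cells (811 higher, 905 lower), 1689 in light zone-like cells (729 and 960), 3819 in S phase-like cells (1829 and 1990) and 2425 in G2/M-like cells (1186 and 1239).

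The change depended on the zone for some genes. Mcm6, which encodes a part of the replicative helicase, changed by -0.04 in dark zone-like and 0.45 in light zone-like cells, a difference of 0.51 in the joint model, and Mcm4 by 0.53 more in light zone-like cells (edgeR adjusted p = 0.00588). The S phase list as a whole had a median change of -0.22 in dark zone-like and 0.28 in light zone-like cells (camera adjusted p of the difference 3.6e-49, and p = 0.026 with an estimated correlation). The complement receptor gene Cr2, the inhibitory coreceptor gene Cd72 and Il4i1 changed by -0.55, -0.36 and -0.38 on the log2 scale, light zone-like minus dark zone-like. Of 10461 tested genes, 278 differed (143 more positive in light zone-like cells, 135 less). The count fell to 167 without WT 4 (85 more positive, 82 less), 160 without KO 1 (60 and 100) and 167 without KO 2 (85 and 82). The DESeq2 Wald test called 83 (29 and 54), so the even split did not hold in every setting.

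Female cells were much rarer in KO, and many genes of the activation groups rose in male cells without a similar rise in female cells. Female cells made up 37.8% ± 1.14 of GC B-like cells with a call in WT and 5.48% ± 0.229 in KO (SD, n = 4 libraries each, adjusted exact p = 0.0429). Light zone markers had a median log2 change of 0.39 in male and 0.02 in female cells (camera adjusted p of the difference 4.9e-18, and p = 0.0506 with an estimated correlation). CD40 and NF-kB genes had 0.25 and -0.19 (camera adjusted p = 1.2e-21, and 0.0475 with an estimated correlation), and immediate early genes 0.30 and -0.01 (6.0e-11 and 0.0475 by the same tests). Cholesterol synthesis was closer, with 0.49 and 0.38 (camera adjusted p = 0.0119, and 0.114 with an estimated correlation). Dtx1 fell by 1.03 in male and 0.39 in female cells, and Fos changed by 1.58 and 0.30. Ighg2b (-2.68 and 0.26), Brip1 (-1.06 and 0.09) and Rilpl2 (0.84 and -0.22) had opposite signs in male and female cells, but none of these 3 female values passed edgeR (adjusted p = 0.648, 0.526 and 0.615), and the difference between the sexes was not called for Rilpl2 (adjusted p = 0.0615). Other named genes turned in female cells and passed edgeR there. Bcl3 (-0.60, adjusted p = 3.7e-08), Cd72 (-0.37, 2.1e-07), Bcl2a1b (-0.34, 8.3e-06), Bcl2a1d (-0.44, 1.6e-05), Nfkbia (-0.24, 3.9e-04) and Ifi47 (-0.25, 0.0476) were lower, and Nuggc (0.18, 0.0013) was higher. By edgeR, 4987 genes were called in male and 2443 in female cells. The sex difference of the change was called for 1179 of 12409 genes (613 more positive in male cells, 566 less). Of 11049 genes tested in both, 1664 were called in both, of which 697 rose in both, 852 fell in both and 115 (6.91%) went opposite ways.

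Shares of switched isotypes lay apart between the genotypes without passing the adjusted test. In KO GC B-like cells fewer cells carried Ighg2b (0.632% ± 0.0814 against 2.07% ± 0.255 in WT) or Ighg3 (0.481% ± 0.0882 against 1.74% ± 0.175), and more carried Ighg1 (4.47% ± 0.374 against 3.66% ± 0.208). Unswitched cells, with Ighm or Ighd, made up 94.4% ± 0.421 in KO and 92.4% ± 0.329 in WT (SD, n = 4 libraries each). For these 4 isotypes the exact p was 0.0286 and the adjusted p 0.05, which is not below the threshold. Leaving out 1 library in turn gave adjusted exact p-values of up to 0.1 for these 4 isotypes and 0.12 for Ighg2c. Without KO 4 they were 0.04 for all 5. Ighg2c with all libraries made up 0.0444% in KO and 0.101% in WT (adjusted exact p = 0.08). Igha was called in cells of 2 WT and 1 KO libraries and Ighe in 1 WT library. Among cells with a call, a count of 0 allows a share of up to 0.0550% to 0.0584% in a WT and 0.0444% to 0.0515% in a KO library. Cells without a call are outside this limit. In male cells alone the direction for Ighg1 turned, with 3.32% ± 0.362 in KO and 5.13% ± 0.370 in WT, and unswitched cells made up 95.8% and 90.4% (adjusted exact p = 0.04 for both). In female cells alone Ighg1 cells made up 24.4% ± 2.91 in KO and 1.73% ± 0.179 in WT (adjusted exact p = 0.0667). Other directions turned there, with 70.1% and 94.95% for unswitched (adjusted exact p = 0.0667), 3.01% and 1.52% for Ighg2b (0.0667), 2.19% and 1.72% for Ighg3 (0.55) and 0.254% and 0.0694% for Ighg2c cells (0.6).

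Heavy chain variable gene usage was more even in KO. The inverse Simpson index, the effective number of equally used Ighv genes, was 39.4 ± 0.722 in KO and 29.0 ± 0.470 in WT (SD, n = 4 libraries each, exact p = 0.0286). The most used Ighv gene held 6.67% ± 0.0671 of KO and 8.26% ± 0.235 of WT cells with a call (exact p = 0.0286). Among genes chosen after their values were seen, Ighv1-81 was used by 5.33% of KO and 8.06% of WT cells, Ighv1-9 by 4.61% and 7.73%, Ighv1-55 by 3.26% and 6.34%, Ighv8-8 by 6.67% and 4.54%, and Ighv1-72 by 3.10% and 1.56% (adjusted exact p = 0.0408 for each). The light chain gene Igkv1-117, chosen in the same way, was used by 4.26% of KO and 8.38% of WT cells. Clones were not resolved, and the number of mice behind these shares is not stated.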

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

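All tests of explanations below were chosen after the results were seen, except the draw of smaller numbers of male cells and the counts over other splits of the libraries. The comparisons of male with female cells, and of Dtx1 between cell classes, were also chosen afterwards.

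Dtx1 was lower in the GC B-like cells of KO libraries while the mean of naive-like cells was not lower and that of T cell-like cells fell less (144 to 121 CPM, exact p = 0.371): relative to GC B-like cells, KO minus WT, the difference was 1.12 on the log2 scale for naive-like and 0.64 for T cell-like cells (exact p = 0.0286, 0.0429 adjusted, for each). Free RNA released by GC B-like cells is excluded as the source, since the naive-like level in KO lay 0.912 above that of GC B-like cells on the log2 scale, and such RNA brings it no higher than theirs. For the naive-like cells, male cells alone gave 1.17 (exact p = 0.0286, but 0.0857 adjusted over 3 classes). This argues against another mix of male and female cells without excluding it, as it rests on 63 Dtx1 UMIs in 252 male KO cells. Male T cell-like cells gave 0.47 (exact p = 0.343). A deletion limited to cells of the GC response is consistent with the 1.12 and with a memory-like level that kept near the GC level in all cells (0.12, exact p = 0.371), though less so in male cells (0.39, exact p = 0.0571). The fall in neutrophil-like cells (-1.59, exact p = 0.0286) does not follow from a limited deletion but cannot decide against it. That fall rests on 51 Dtx1 UMIs in 215 KO cells, and doublets and free RNA stayed in the data. The labels name no cell-specific deletion, so a limited deletion remains a hypothesis.

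Light zone genes were higher in KO GC B-like cells, and so were immediate early genes by camera (13 of 22 higher and 4 lower, adjusted p = 1.5e-10, but p = 0.0683 with an estimated correlation). A larger light zone-like cluster is excluded as the whole cause, since the light zone list rose inside the 3 other named states, with a lowest median of 0.19 on the log2 scale in dark zone-like cells. With an estimated correlation the call held in S phase-like (p = 0.00235) and G2/M-like cells (p = 0.029) but not in dark zone-like cells (p = 0.0502), and the list did not rise inside light zone-like cells (0.05, camera direction down, adjusted p = 0.441). Handling of the preparations may contribute, since camera called the immediate early list higher in 2 of 3 other classes. These were naive-like (adjusted p = 0.0197, and unadjusted p = 0.0728 with an estimated correlation) and T cell-like cells (adjusted p = 0.00218, and unadjusted p = 0.0123 with an estimated correlation). The list was not called in macrophage-like cells. Other mice in the WT and KO pools may also contribute, and a direct effect of the Dtx1 genotype stays open because no sample separates genotype from preparation. The light zone list had a median of 0.021 in the female cells of the same libraries. This cannot decide on handling, because female cells also differed in make-up. Their ratio of dark zone-like to light zone-like cells was 2.58 in KO and 1.64 in WT, and Ighg1 cells made up 24.4% and 1.73%.

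Many changes differed between male and female GC B-like cells: the interaction was called for 1179 genes. The smaller number of female cells in KO is excluded, since male cells drawn to that number in KO, and to 1512 to 1552 per library against 1765 to 1984 female cells in WT, kept a light zone median of 0.36 on the log2 scale, and of 1267 genes called in them 1149 were also called in the remaining male cells, 0 of these in the opposite direction. A smaller loss of Dtx1 in female cells is excluded as the whole cause, since 6.91% of the genes called in both sexes went opposite ways. Male and female cells come from different mice in any case, so Ighv usage could not test that. Usage differed between male and female cells with a chi-square over degrees of freedom of 4.40 in KO and 13.5 in WT. Whether differences between mice cause the interaction stays open. A biological effect of sex on what Dtx1 does stays open as well, since sex and mouse are not separated in these libraries.

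Single genes differed in their change between the sexes by the interaction test (male minus female, log2). The values were -0.64 for Dtx1, 1.27 for Fos, 0.65 for Sh2d2a, -1.25 for Parm1, 0.81 for Matk, 0.51 for Ier2, 0.46 for Il4i1 and 0.38 for Myc. Among the genes lower in KO they were -2.94 for Ighg2b, -0.52 for Pde2a, -1.15 for Brip1, 0.69 for Grm6, -0.36 for Itgb3 and -0.48 for Cxcr4. The same test called 278 genes between light zone-like and dark zone-like cells, of the named genes with the largest changes only Il4i1 (-0.38). That count was 167 without WT 4, 160 without KO 1 and 167 without KO 2.

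Shares of cells also changed differently in male and female cells. The male-minus-female difference changed from WT to KO by -6.0 percentage points for dark zone-like, 5.94 for light zone-like and -4.38 for G2/M-like cells (adjusted exact p = 0.0464 for these and the following). It changed by 30.2 points for unswitched, -24.4 for Ighg1, -3.49 for Ighg2b and -1.90 for Ighg3 cells. The inverse Simpson index of Ighv usage changed by 3.44.

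Single libraries stood apart from the other 3 of their genotype in 8 of 96 groups of values tested for it, where chance gives about 1 in 20. Neutrophil-like cells were 0.621% in KO 4 and 0.739% to 0.758% in the other KO libraries. Cluster 19 held 0.260% of KO 4 and 0.0800% to 0.101% of the others. Igha was called in 0.0344% of cells in KO 4 and in no cell of the other KO libraries, and Ighe in 0.0193% of cells in WT 4 and in no cell of the other WT libraries. Egr1 measured 37.5 CPM in WT 2 and 40.03 to 40.56 in the others. In KO 1, Ppp1r15a measured 26.6 CPM (25.1 in each of the others), Matk 18.9 (20.4 to 20.7) and Myc 53.6 (47.0 to 47.6).

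Other splits of the 8 libraries into 4 and 4, 35 in all with the real one, gave far fewer called genes. They test only chance differences among libraries. The libraries of a genotype were alike in Ighv usage (chi-square over degrees of freedom 1.02 and 0.941), as parts of 1 pool would be. The sex of the cells differed somewhat among the 4 WT libraries (2.72, chi-square p = 0.0428) but not among the 4 KO libraries (0.621, p = 0.601). Chance differences between mice or pools are therefore not excluded for any result here. Each other split mixes WT and KO libraries, so a genotype difference adds to the spread within its groups and lowers its count. Low counts there therefore do not show how many calls chance alone gives. The highest other split gave 0 against the 5593 genes of GC B-like cells and the 7060 of all cells. It gave 1 in each state, against 1716 genes of dark zone-like, 1689 of light zone-like, 3819 of S phase-like and 2425 of G2/M-like cells. It gave 3 for the zone interaction (real 278), 1 for the sex interaction (1179), 0 for male cells (4987) and 2 for female cells (2443). In all these cases 1 of 35 splits, the real one, gave as many, the smallest share this design allows. For the 12 lists called by camera chance among libraries is not excluded, since the highest other split gave 13 and 4 of 35 splits gave as many. With an estimated correlation the real split gave 5 lists and the highest other split 0, with the same limit as for the gene counts.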

How the results depend on the processing

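Fits on male or female cells alone, clusters made without the changed genes, and the comparison of male with female cells, with each library left out in turn, were chosen after the data had been seen, and the other alternatives before. Of 464 alternatives of the 32 results that answer a comparison, 384 stayed the same, as did 2411 of 2465 for single genes and 435 of 516 for lists. For counts of genes or lists this means within 1.5 times of the main count. For other values it means the same direction and side of the threshold. For shares with a replicate block it means the same direction and a move within the larger SD. Dtx1 stayed lower in KO under all alternatives run, with -0.98 to -0.94 on the log2 scale when 1 library was left out. The genes called in GC B-like cells numbered 4902 to 5598 in the same runs. Depth limits the rare classes and isotypes, and female cells were few in KO. Where no other cause is named for a value below, the cause was not tested.

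The replicate numbers gave no sign of pairs, since libraries with the same number had correlations across genes of 0.33, 0.06, 0.18 and -0.23 (genes are not independent replicates). With a replicate block, 5530 genes were called in GC B-like cells, 6889 in all cells, 1746 in dark zone-like, 1711 in light zone-like, 4038 in S phase-like and 2632 in G2/M-like cells, Dtx1 changed by -0.96 on the log2 scale, and 13 lists were called, with marginal zone markers added. The replicate block kept 164 of 166 results, leaves differences of shares as they are, and its sign-flip p cannot go below 0.125. Oxidative phosphorylation turned direction under it (adjusted p = 0.923). The zone interaction has the library as block already and was not run with this one.

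Counts of genes moved by more than 1.5 times in these cases. Female cells alone gave 2443 genes. The DESeq2 Wald test gave 855 genes in dark zone-like, 986 in light zone-like and 1504 in G2/M-like cells and 83 for the zone interaction. Male cells alone, with fewer cells per state, gave 1113 in dark zone-like and 1491 in G2/M-like cells. Leaving out 1 library gave 160 to 255 genes for the zone interaction, with 167 without WT 4, 160 without KO 1 and 167 without KO 2.

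In female cells alone the differences of shares, KO minus WT in percentage points, were 4.76 for GC B-like, 3.32 for dark zone-like, -1.32 for light zone-like, 3.12 for S phase-like, 4.64 for G2/M-like, -4.41 for naive-like, -1.06 for memory-like, -0.426 for T cell-like, -0.0712 for macrophage-like and -0.0930 for neutrophil-like cells, 1.27 for cluster 11 and 0.0180 for cluster 19. The ratio of dark zone-like to light zone-like cells differed by 0.948 there. None of these passed the exact test after adjustment. GC B-like, dark zone-like, G2/M-like, naive-like and memory-like cells and the ratio reached the smallest possible exact p of 0.0286 (0.0619 adjusted). Not passing there does not show a lack of difference. The dark zone-like, light zone-like, G2/M-like, ratio, memory-like and cluster 19 values had turned direction. In male cells alone the differences whose direction or call changed were 0.255 for G2/M-like, 0.791 for memory-like and -0.222 for neutrophil-like cells. The S phase-like difference was 0.630 at resolution 0.5, -0.392 at resolution 1.5, 1.54 with thinned cells and -0.119 without the changed genes. The G2/M-like difference was 0.460, 0.160 and 1.16 under the first 3 of these, called only with thinned cells (adjusted exact p = 0.0321). The memory-like difference was 1.00 at resolution 1.5. The neutrophil-like difference was -0.0824 with the strict cell filter, 0.128 at resolution 0.5 and -0.206 without the changed genes. Some called differences kept their call but moved by over 1.5 times. The macrophage-like one went from -3.15 to -1.07 with the strict cell filter, -1.06 in thinned cells and -1.43 in male cells, the naive-like one from -7.49 to -3.67 at resolution 1.5, and the ratio from -0.828 to -0.445 in thinned cells. The light zone-like one went from 3.80 to 5.98 at resolution 1.5, 5.72 in thinned cells and 1.34 without the changed genes.

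Leaving out 1 library gave 2.26 to 3.44 points for S phase-like cells (not called without WT 1, WT 2, WT 3 or WT 4, at 2.58, 2.95, 2.77 and 3.03) and -0.531 to 0.390 for G2/M-like cells (above 0 without WT 3, 0.146, WT 4, 0.208, and KO 4, 0.390). It gave 0.273 to 0.435 for memory-like cells (called without WT 1, 0.435), -3.63 to -2.94 for macrophage-like cells, -0.200 to -0.142 for neutrophil-like cells and 0.507 to 0.706 for cluster 11. The last 3 were not called without KO 1 (-3.21, -0.183 and 0.524), KO 2 (-3.20, -0.187 and 0.602), KO 3 (-3.17, -0.181 and 0.630) or KO 4 (-3.01, -0.142 and 0.657). No dark zone-like cluster was named at resolution 1.5, no memory-like cluster at resolution 0.5, in thinned cells or without the changed genes, no neutrophil-like cluster in thinned cells and no dark zone-like cluster without the changed genes, and clusters 11 and 19 have no counterpart in other clusterings, so these gave no value.

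For the isotypes in the order unswitched, Ighg1, Ighg2b, Ighg2c and Ighg3, the strict cell filter gave 2.10, 0.760, -1.49, -0.0696 and -1.28 points and male cells alone 5.37, -1.81, -2.0, -0.0950 and -1.43, all called, with Ighg1 turned in male cells. Female cells alone gave -24.9 for unswitched, 1.49 for Ighg2b, 0.184 for Ighg2c, 0.467 for Ighg3 and 0.0903 for Igha, all turned and none called. Leaving out 1 library gave 1.82 to 2.13, 0.671 to 0.938, -1.52 to -1.34, -0.0701 to -0.0467 and -1.35 to -1.21 in the same order, with all 5 called without KO 4 (1.82, 0.938, -1.41, -0.0701 and -1.25).

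Among the named genes, 35 alternatives ended a call and 19 turned the direction, 21 and 18 of these in female cells alone. There the log2 change turned for Rilpl2 (-0.22), Ighg2b (0.26), Brip1 (0.085), Nfatc1 (-0.058), Cd72 (-0.37), Relb (-0.047), Bcl3 (-0.60), Nfkbia (-0.24), Bcl2a1b (-0.34), Bcl2a1d (-0.44), Ifi47 (-0.25), Kdm6a (0.0094), Nuggc (0.18), Cenpf (0.094), Lck (-0.085), Trac (-0.14), Car2 (-0.11) and Pecam1 (0.021). Of these, Cd72, Bcl3, Nfkbia, Bcl2a1b, Bcl2a1d, Ifi47 and Nuggc passed edgeR in female cells. Bcl2a1b also turned with an equal weight of states (-0.015).

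Camera called 20 lists in all cells, 5 lists with an estimated correlation in GC B-like cells, and fry called 28. Lists that turned direction in female cells alone were, with the adjusted p there, anergy (0.00102), CD40 and NF-kB (0.00179), T cell help (0.589), apoptosis (0.0139), hypermutation (0.469), interferon (0.581), immediate early (0.626), mTORC1 (0.751), TGF beta (0.535), GC core (1.3e-05), dark zone (0.132), G2/M (1.4e-07) and T cell markers (0.704). With an estimated correlation none of these was called in female cells (for those below the threshold p = 0.0885, 0.318, 0.0968, 0.106 and 0.125, in this order). In all cells they were p53 targets (0.502), hypermutation (0.489), interferon (0.00706), TGF beta (0.407), GC core (0.201), G2/M (0.0147), T cell (1.2e-11) and dendritic cell markers (0.344), none of them called with an estimated correlation (p = 0.186 for interferon, 0.405 for G2/M and 0.060 for T cell markers). In male cells alone they were p53 targets (0.836) and erythroid markers (0.977), and with fry TGF beta (0.974). With 1 library left out, the adjusted p ran from 0.816 to 0.999 for p53 targets (turned without WT 3, 0.909, and KO 4, 0.999), from 0.423 to 0.916 for oxidative phosphorylation (turned without WT 1, 0.587, WT 2, 0.816, KO 2, 0.631, and KO 3, 0.916), from 0.880 to 0.999 for TGF beta (turned without WT 4, 0.889, KO 3, 0.958, and KO 4, 0.999) and from 0.595 to 0.994 for erythroid markers (turned without WT 4, 0.646, and KO 3, 0.994). None of these 4 lists was called.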

Other observations

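The tests of single unnamed clusters and of genes near Dtx1 were chosen after the results were seen. Gene groups that the camera test did not call held members that changed in KO GC B-like cells. Of all 13105 tested genes 5593 were called, so called members alone do not set a list apart. Of 11 marginal zone markers 6 fell and 1 rose (adjusted p = 0.0750), among them the complement receptor gene Cr2 (-0.54 on the log2 scale), and the list was called without WT 3 (adjusted p = 0.0392, at most 0.0980 without another library). Of 14 naive B cell markers 7 fell and 4 rose (adjusted p = 0.0887), although Fcer2a, the gene of CD23, rose by 0.47. Of 11 macrophage markers 5 fell and 1 rose (adjusted p = 0.0887), with Vcam1 at -1.33, and the list was called without KO 1 (adjusted p = 0.0354, at most 0.155 without another library). Of 13 plasma cell markers 4 rose and 3 fell (adjusted p = 0.0887). S phase markers rose in 16 and fell in 2 of 24 (adjusted p = 0.102), with Mcm6 at 0.18. Memory markers rose in 4 and fell in 5 of 15 (adjusted p = 0.135), with the corepressor gene Tle3 at -0.64. Migration genes rose in 6 and fell in 10 of 21 (adjusted p = 0.135), with the integrin gene Itga4 at -0.56. B lineage transcription factors rose in 6 and fell in 13 of 29 (adjusted p = 0.437), with Tbx21, which encodes T-bet, at 1.17 and Pax5 at -0.40.

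Notch pathway genes, the pathway Deltex proteins are linked to, rose in 7 and fell in 8 of 27 (adjusted p = 0.520), and Deltex family and partner genes rose in 3 and fell in 6 of 11 (adjusted p = 0.135), with the ubiquitin ligase genes Cbl at -0.33 and Cblb at -0.22. B cell receptor signalling genes rose in 10 and fell in 15 of 30 (adjusted p = 0.198), with Cd72 at 0.59. T cell help and antigen presentation genes rose in 11 and fell in 5 of 21 (adjusted p = 0.151), with H2-DMb1 at -0.56. Hypermutation, switching and repair genes rose in 7 and fell in 11 of 30 (adjusted p = 0.132). GC core markers rose in 3 and fell in 5 of 12 (adjusted p = 0.151), with S1pr2 at 0.21. The adjusted p was 0.199 for dendritic cell markers (2 of 4 rose), 0.30 for anergy genes (3 rose and 4 fell of 12), 0.364 for stromal markers (2 of 3 fell), 0.523 for apoptosis regulators (7 rose and 7 fell of 26), 0.637 for G2/M markers (3 rose and 6 fell of 26) and 0.719 for interferon genes (7 rose and 4 fell of 27). It was 0.726 for neutrophil markers (0 of 3 passed), 0.746 for erythroid markers (1 of 5 rose), 0.950 for p53 targets (6 rose and 4 fell of 19), 0.950 for oxidative phosphorylation (7 rose and 2 fell of 46) and 0.963 for TGF beta and cytokine receptors (7 rose and 8 fell of 22). The median, the mean and the test differ in sign for anergy, p53 targets, oxidative phosphorylation, B lineage transcription factors, TGF beta, GC core, interferon and erythroid lists. Adjusted over the list alone, the counts that differ are 17 and 5 for S phase, 5 and 6 for memory, 3 and 7 for Deltex, 7 and 10 for migration, 1 and 6 for macrophage, 6 and 15 for B lineage factors, 6 and 5 for p53 and 3 and 0 for oxidative phosphorylation.

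Clusters of GC B-like cells without a zone or phase name also differed in size. Cluster 7, led by Mxd4 and Ddit4, held 16% ± 0.288 of WT and 11.3% ± 0.681 of KO cells (SD, n = 4 libraries each, adjusted exact p = 0.0381), and cluster 13, led by Pxdc1 and Lta, held 5.76% and 8.92%. Near Dtx1, 16 of 385 tested genes within 20 Mb on either side changed by at least 1.5-fold (4.16%), with Rilpl2 and Sap25 among them, against 4.36% elsewhere, and 54.8% of windows elsewhere were as high.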
